A study of Mus musculus with 12 samples.

How the data were processed

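Total RNA of sorted female and male mouse blastocysts was measured by competitive hybridisation on 2 Agilent array designs. Per the labels, dams of 8 weeks were superovulated and mated with males written XGFPY, embryos at the 4-cell stage were flushed 55 hours after the injection of chorionic gonadotropin and cultured for 38 hours, and embryos with and without green fluorescence were taken as females and males. Yeast tRNA was added as a carrier during extraction, and RNA was labelled by linear amplification with Cy3 or Cy5, per the labels.

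The deposited values are log10 ratios of the 2 channels of each array. Per the series design text, scans were processed with Agilent Feature Extraction version 7.5, arrays were then combined with a Rosetta program, and each hybridisation was repeated with the dyes exchanged. The values used here are those of single arrays, not combined ones. Background correction and dye normalization settings are not given in the sources used here. The log10 scale was read from the values, which lie between −2 and 2: 10 of the 12 arrays reached exactly −2 and 3 reached exactly 2. These limits do not show which of the named programs wrote the values. All arrays were already centred: their medians lay between −0.000711 and 0 log10 units. The direction of the ratio is not given either. It was read as Cy5 over Cy3, as Feature Extraction writes it. A set of 321 features of 22K-1 and 323 of 22K-2 had log10 ratios under −0.7 on all 6 arrays whichever sex was in Cy5, so the submitters had not turned the ratios to 1 sex over the other. These features are called control-like here. There were 0 columns of values without a matching sample.

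Arrays were grouped by the source of each channel. The title of 1 array of preparation 19 on 22K-1 names male RNA on both sides, while its channel sources give male RNA in Cy3 and female RNA in Cy5. It was grouped by the channel sources. The ratio of each array was multiplied to the log2 scale and turned to female over male, and the 2 arrays of a preparation, which share their RNA extracts, were averaged, so that n = 3. The pairing of the 2 arrays comes from the preparation number in the labels. The 3 means were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, eBayes without trend), with Benjamini-Hochberg adjustment over the 22575 features of a set and a threshold of 0.05. The p-values rest on the spread between 3 preparations. The prior degrees of freedom of the variance were 1.31 on 22K-1 and 1.42 on 22K-2. An exact sign-flip test of 3 preparations cannot give a p below 0.25. No batch was given in the sources used here.

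The test, the alternatives and the rule for named features were chosen before the data were examined. The rule names, in each direction and array set, the features with the smallest unadjusted p and the same sign on all 6 arrays where fewer than 3 features pass the threshold. As the files do not pair features with genes, only the first in each direction is printed by number. The planned fits of X-linked and autosomal genes, of sex-linked control genes, of gene lists, of the X-linked share of calls and of genes measured by both array sets need gene names and were not run. The reference table of mouse genes supplied for GRCm38.p6 has no feature numbers and was not used. The alternatives run were centring or scaling of arrays, filters on exact zeros and on the spread between dye orientations, fits of 6 arrays with the preparation as a block (duplicateCorrelation) with and without a dye term, arrays of 1 dye orientation, robust eBayes, adjustment over both sets and the omission of each preparation. Where a preparation was left out of the dye-term fit, the correlation within preparations was the one estimated from all 6 arrays, so the omitted preparation still entered through it. Counts of features at least 1.5-fold one way on all 6 arrays, and all values without the control-like features, were added after the data had been seen. The lower fold of those counts was first set at 1.25 and was changed to 1.2 for reasons of reporting format, after the counts at 1.25 had been seen. The change applies to the share of features near equality and to the shift of all ratios too, and the values at both folds are given.

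The fits were tested on simulated data, with the variance of each feature drawn from its limma posterior. With 200 of 22575 features changed, the fit of preparation means recovered 73 of 100 at 2-fold and 98 of 100 at 8-fold in arrays simulated after 22K-1, and 75 and 95 of 100 in those simulated after 22K-2. With only 20 changed, it recovered 1 of 10 at 2-fold in each set, and at 8-fold 10 of 10 for 22K-1 and 9 of 10 for 22K-2. The fit of 6 arrays with a dye term and a block recovered 7 and 5 of 10 at 2-fold and 10 of 10 at 8-fold in both, and also called 4 unchanged features for 22K-1 and 1 for 22K-2. With 200 changed it called 18 and 7 unchanged features. The count over all 6 arrays at 1.5-fold included 2 unchanged features for 22K-1 and 4 for 22K-2 with 20 changed, and 2 for each with 200 changed. The noise model was revised after its results had been seen. In the version used before the last, which drew the variances of the sex part and the dye part of a feature separately, from 4 to 19 unchanged features met the 1.5-fold count in 20 runs for 22K-1 and from 4 to 12 for 22K-2. Simulated variances were more alike than the measured ones, with prior degrees of freedom of 1.61 and 1.73 with 20 changed features.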

Results

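Blastocysts are embryos just before implantation, built of an inner cell mass and an outer trophectoderm layer. RNA of female and male mouse blastocysts at E3.5 was compared on 2-colour Agilent arrays, on which the female and the male RNA of a preparation were labelled with different dyes and hybridised together. Per the labels, embryos were sorted into females, which carried a green fluorescent marker, and males, which did not, and over 200 embryos of 1 sex went into an extract. Effects of the marker and of sex cannot be told apart here, as the marker went with sex in every preparation. There were 3 independent preparations, numbered 18, 19 and 23. Each was hybridised in both dye orientations on each of 2 array sets, 22K-1 and 22K-2, which gave 6 arrays per set and 12 arrays in all. Every array listed a value for all 22575 features of its set. Exact zeros numbered from 600 to 778 per array on 22K-1 and from 480 to 607 on 22K-2, and 208 and 199 features were listed at 0 on all 6 arrays. The number of preparations, 3, limits the precision of each mean. The features are identified by a number alone. Gene names and chromosomes were not used here, and a number stands for a feature within its own array set.

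The comparison asked which transcripts differ in level between female and male embryos before implantation. For most features the ratio lay close to equality. Signal over background was not analysed, so features without a detectable transcript, if any, are counted too. Of the 22254 features of 22K-1 that did not resemble control spots, 94.0% had a mean ratio within 1.2-fold of equality, and of the 22252 such features of 22K-2, 94.7% did. Within 1.25-fold, the bound first used, the shares were 96.2% and 96.6%. Without features that had an exact 0 on any array, the shares within 1.2-fold were 95.2% and 95.6%. The median SD of a feature over the 3 preparations was 0.102 log2 units on 22K-1 and 0.103 on 22K-2.

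On 22K-1 a small number of features stood apart on every array. Feature 18524 had the smallest p of the set, with a mean log2 ratio of female over male of 3.17 ± 0.097 (SD, n = 3 preparations), which is 8.97-fold. This direction, like every direction given here, rests on reading the deposited ratio as Cy5 over Cy3, the convention of the scanner software that the submitters name. It is therefore likely but not stated by the submitters. If the ratio runs the other way, every value given as higher in females is higher in males, and the reverse. The preparation means of feature 18524 were 3.09, 3.28 and 3.13, and its 6 arrays lay between 2.90 and 3.65. Among features lower in females on all 6 arrays, feature 5208 had the smallest p, with a mean log2 ratio of −0.81 ± 0.021 (SD, n = 3 preparations), or 1.76-fold higher in males. In all, 4 features were at least 1.5-fold higher in females on each of the 6 arrays, with mean differences from 1.66-fold to 8.97-fold. Another 4 were at least 1.5-fold higher in males on each array, from 1.76-fold to 8.81-fold. The most extreme of those had a mean log2 ratio of −3.14, with an SD of 0.455 over the 3 preparations. Counts of this size also arose from unchanged features in 1 of the noise simulations, which gave from 4 to 19 for 22K-1 and from 4 to 12 for 22K-2. Sizes and SDs of the simulated features were not compared. With the sexes exchanged within a preparation, which leaves that model unchanged, the measured arrays of both sets gave 0.

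No feature of 22K-1 passed an adjusted p of 0.05 when the preparation means were tested with limma and Benjamini-Hochberg adjustment. The adjusted p of feature 18524, higher in females on 6 of 6 arrays, was 0.0858, and that of feature 5208, lower in females on 6 of 6 arrays, was 0.478. When features with an exact 0 on any array were left out of that limma test, 1 feature passed. Feature 18524 then had an adjusted p of 0.016 and feature 5208 one of 0.308. At an unadjusted p under 0.05 there were 1225 features, 522 higher in females and 703 higher in males, where 1129 would be counted by chance. When all 6 arrays entered the limma fit with a dye term and the preparation as a block, 6 features passed, 4 higher in females and 2 higher in males. In simulated arrays with 20 changed features that fit also called 4 unchanged ones. Feature 18524 had an adjusted p of 0.00829 in that fit and feature 5208 one of 0.00938. Without any 1 of the 3 preparations that fit called 0 features. With the same block and no dye term, 20 features passed, 15 of them higher in females.

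On 22K-2 the features that stood apart at 1.5-fold on all 6 arrays were higher in females under the same reading. There were 14 that were at least 1.5-fold higher in females on each of the 6 arrays and 0 that were as much higher in males. At 1.2-fold on all 6 arrays, 4 features were higher in males. Without preparation 23 the count at 1.5-fold rose to 25 higher in females, and without 1 of the 3 preparations from 1 to 2 were higher in males. The mean differences of the 14 ran from 1.65-fold to 24.6-fold with a median of 4.06-fold, and 7 of them exceeded 2-fold on every array. Feature 15154 had the smallest p, with a mean log2 ratio of 4.57 ± 0.248 (SD, n = 3 preparations), or 23.7-fold. Its preparation means were 4.38, 4.85 and 4.47, and its 6 arrays lay between 4.19 and 4.88. Among features lower in females on all 6 arrays, feature 20365 had the smallest p. Its mean log2 ratio was −0.52 ± 0.015 (SD, n = 3 preparations), or 1.43-fold higher in males, while its single arrays ran from −0.84 to −0.17.

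In the limma test of the preparation means, 0 features of 22K-2 passed an adjusted p of 0.05. Feature 15154, higher in females on 6 of 6 arrays, had an adjusted p of 0.241, and feature 20365, lower in females on 6 of 6 arrays, one of 0.563. When features with an exact 0 on any array were left out of that test, 3 features passed. The adjusted p of feature 15154 was then 0.0271 and that of feature 20365 was 0.327. An unadjusted p under 0.05 was reached by 1482 features, 591 higher in females and 891 higher in males, against 1129 by chance. With all 6 arrays, a dye term and the preparation as a block, 13 features passed, 12 of them higher in females and 1 higher in males. In that fit of 6 arrays feature 15154 had an adjusted p of 0.00107 and feature 20365 one of 0.187. Of the 14 features that were at least 1.5-fold higher in females on every array, 8 were among the 13. The fit called 0 features without preparation 18 or without preparation 23, and 3 without preparation 19. With the block and no dye term, 35 features passed, 29 of them higher in females.

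**Figure D1:**
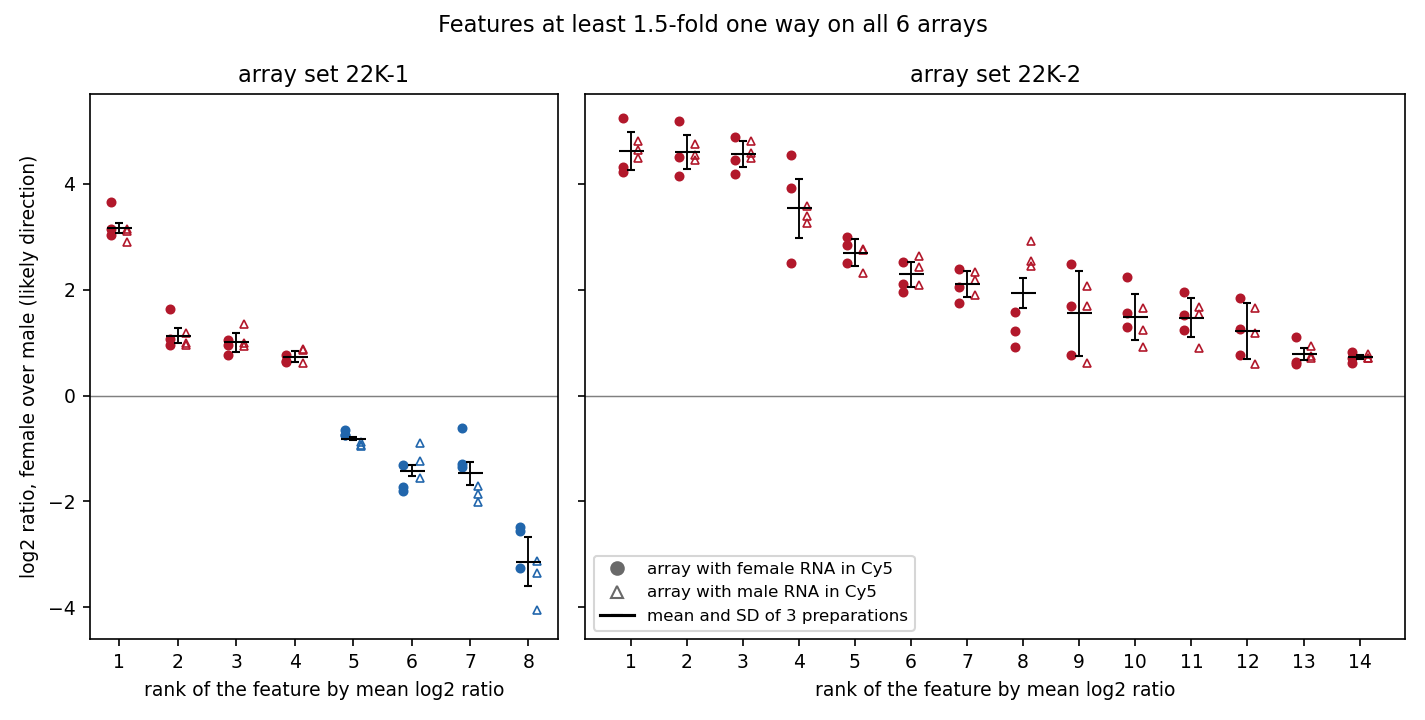
Log2 ratio of female over male, in the likely direction, of each feature that was at least 1.5-fold one way on all 6 arrays of its set, ranked by its mean on the x axis, for 22K-1 (left) and 22K-2 (right). Filled circles are arrays with female RNA in Cy5, open triangles are arrays with male RNA in Cy5, and the black bars are the mean and SD of the 3 preparations. The 4 features higher in males (blue) are on 22K-1, and 3 features of 22K-2 lie above a log2 ratio of 4 on all 6 arrays.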

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

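The tests of explanations in this part were chosen only after the results had been seen. For 1405 features of 22K-1 and 2294 features of 22K-2, the ratio of female over male differed between the arrays with female RNA in Cy5 and those with male RNA in Cy5, at an adjusted p under 0.05 of the dye term in the limma fit of 6 arrays. The mean deposited ratio of these features was above 0 for 376 and below 0 for 1029 on 22K-1, and above 0 for 730 and below 0 for 1564 on 22K-2. The counts below 0 include all 321 and 323 control-like features, which lie below 0 by definition. Without them the counts were 376 above and 708 below 0 on 22K-1, and 730 above and 1241 below on 22K-2. The orientation is not a biological group, and no biological explanation was tested.

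The tables argue against control spots alone as the source, since control-like features were 22.8% of the affected ones on 22K-1 and 14.1% on 22K-2. They also argue against an array with exchanged labels. Of the features at least 1.5-fold one way on 5 arrays, the lowest share that kept its direction on the array left out was 88.9% on 22K-1 and 93.3% on 22K-2. These shares rest on few features. On 22K-1, 4 of 4 higher in females and 4 of 5 higher in males kept it, and on 22K-2, 14 of 14 and 0 of 1. On the array whose title names male RNA on both sides, 4 of 4 features higher in females and 4 of 4 higher in males kept their direction. A dye bias of each feature may account for the pattern: across features, the dye part of the ratio correlated between preparations with r of at least 0.312 on 22K-1 and 0.442 on 22K-2, where the part turned to female over male reached at most 0.204 and 0.298. Features are not independent replicates, so these correlations carry no p. The dye term rests on agreement of the dye part between the same preparations, so the correlations are not separate support.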

How the results depend on the processing

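The counts at 1.2, 1.5 and 2-fold, those without control-like features and the omissions of a preparation from the dye-term fit were chosen after the results had been seen. Against 0 features in each set on preparation means, the fits of 6 arrays with the preparation as a block called 6 on 22K-1 and 13 on 22K-2 with a dye term, and 20 and 35 without one. The correlation within preparations was estimated at 0.156 and 0.153 with the dye term and at −0.195 and −0.210 without it. Each estimate was applied to all features, also to those without a dye effect, so the counts without a dye term need more care. Leaving out features with an exact 0 on any array gave 1 and 3 calls, feature 18524 of 22K-1 and feature 15154 of 22K-2 among them, and the cause was not tested. Arrays with female RNA in Cy5 alone gave 297 and 432 calls, of which 247 and 322 were control-like. Arrays with male RNA in Cy5 alone gave 24 and 348, of which 23 and 310 were control-like. By construction a dye effect does not cancel there. Centring, scaling, the filter on spread between orientations, robust eBayes, the removal of control-like features, adjustment over both sets and the omission of any 1 preparation gave 0 calls in both sets. Without 1 preparation, the dye-term fit, with fewer arrays, called 0 features on 22K-1 and from 0 to 3 on 22K-2, with the block correlation of all 6 arrays.

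Features higher in females on all 6 arrays numbered 4 on 22K-1 and 14 on 22K-2 at 1.5-fold, 24 and 43 at 1.2-fold, and 1 and 7 at 2-fold. Those higher in males numbered 4 and 0 at 1.5-fold, 8 and 4 at 1.2-fold, and 1 and 0 at 2-fold. At 1.25-fold, the setting first used and replaced by 1.2-fold after its counts were seen, they were 17 and 33 higher in females and 5 and 4 higher in males. On the 4 arrays left without 1 preparation, from 4 to 9 (most without preparation 18) and from 15 to 25 (most without preparation 23) were higher in females, and from 4 to 5 and from 1 to 2 were higher in males. Fewer arrays make the rule easier to meet. Alternatives that need gene names were not run. Scaling used the median absolute value, as the planned function gives no value for arrays with a median of 0. Signal over background was not analysed here.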

Other observations

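The tests in this part were chosen only after the results had been seen, and the features described were chosen by their values. On 22K-2, 3 features, feature 15154 among them, had nearly equal mean log2 ratios of 4.62, 4.60 and 4.57, with SDs over the 3 preparations of 0.361, 0.323 and 0.248. The next feature had 3.54, with an SD of 0.564. On any 1 array the 3 features lay within 0.365 log2 units of each other, while each of them ranged over at least 0.698 units across the 6 arrays. Whether the 3 features belong to 1 gene is unknown here.

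Among features at least 1.2-fold one way on all 6 arrays, more were higher in females than in males, 24 against 8 on 22K-1 and 43 against 4 on 22K-2. With no limit on size, the features of 1 sign on all 6 arrays were nearly even, 400 against 369 and 434 against 371, and at an unadjusted p under 0.05 more were higher in males, 703 against 522 and 891 against 591. The directions rest on the likely reading of the ratio, and under the other reading females and males change places throughout. Of features at least 1.2-fold higher in females on the 4 arrays of 2 preparations, the lowest share that kept this direction in the preparation left out was 72.5% on 22K-1 and 77.8% on 22K-2, both for preparation 23, where the median log2 ratio was 0.16 against 0.53 in the choosing preparations on 22K-1 and 0.25 against 0.57 on 22K-2. Of those higher in males the lowest shares were 73.3% and 54.5%. Noise of single preparations alone would let about as many features turn as keep their direction in the preparation left out. For features higher in females the shares that kept it ran from 72.5% to 95.1% on 22K-1 and from 77.8% to 94.5% on 22K-2. For those higher in males they ran from 73.3% to 90.9% on 22K-1 and from 54.5% to 82.4% on 22K-2. On 22K-2 these values argue against such noise as the only source of features higher in females. On 22K-1 such noise cannot be told apart by the lowest shares, 72.5% and 73.3%, the second of which is 11 of 15 features. On 22K-2 the lowest share of those higher in males was near even. Features are not independent, so the shares carry no p, and they do not say whether a kept direction comes from sex. A shift of all ratios of 0.09 log2 units on 22K-1 or 0.125 on 22K-2 would even out the counts at 1.2-fold. After taking off that shift, 10 features were at least 1.5-fold higher in females on all arrays of 22K-2 and 0 higher in males, and on 22K-1 the counts were 3 and 4. The 10 against 0 on 22K-2 argue against a shift of all ratios as the only source of the excess there, since it would even them out too. On 22K-1 a shift cannot be told apart from a sex difference by these counts. Features are not independent in either set, the arrays were centred before deposit, and the counts at 1.5-fold on 22K-1 were even before the shift too. At 1.25-fold, the setting first used, the shifts that evened the counts were 0.13 and 0.165, and the counts at 1.5-fold after them were again 3 and 4 on 22K-1 and 10 and 0 on 22K-2. A difference between the sexes remains open.

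The splits are too few for a share under 0.05. On 22K-1, 8 features and on 22K-2, 14 features were at least 1.5-fold one way on all 6 arrays under the real grouping, which was 1 of 10 splits, and the highest of the other splits gave 0 in each set. Only 4 of the 10 splits keep the 2 arrays of a preparation as a pair of exchanged dyes, and among these the real one is 1 of 4. In the fit with a dye term, the real grouping gave 6 and 13 features, and the highest of the other 3 ways of exchanging the sexes within preparations gave 0 in each set, so 1 of 4 gave as many. On preparation means all 4 of the 4 gave 0. The number of unchanged features that meet the 1.5-fold count in simulated arrays depended on the noise model. With 1 variance per feature it was 2 for 22K-1 and 4 for 22K-2 beside 20 changed features and 2 for each beside 200, and it was from 4 to 19 and from 4 to 12 over 20 runs with separate variances for the sex and dye parts. The measured 8 of 22K-1 lies within the range of the second model, and the measured 14 of 22K-2 lies above it. That model stays the same when the sexes of a preparation are exchanged. Those splits of the measured arrays gave 0 in each set, below its lowest count of 4, which argues against that noise level.

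A candidate explanation of features higher in females is 2 copies of an X-linked gene against 1, with equal output per copy, which gives at most a 2-fold ratio. Of the 18 features at least 1.5-fold higher in females on all arrays, 8 exceeded 2-fold on all 6 arrays, 1 on 22K-1 and 7 on 22K-2, which this explanation alone does not allow in the likely direction. Another 3 exceeded 2-fold in all 3 preparation means, and by more than their SD in the mean. A dye effect of equal size on both arrays of a preparation cancels in those means, but one that differs between them does not. Each of these 3 fell under 2-fold on at least 1 of the 6 arrays, and they were chosen as high by the same values, so they weigh less. If the ratio runs the other way, the features higher in females are the other 4 of 22K-1, of which 1 exceeded 2-fold on all 6 arrays and 2 in the preparation means alone, and 0 of 22K-2. For the remaining 7 in the likely direction it cannot be told apart from other causes, because their chromosomes are unknown here.

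Across the features that were not control-like, the ratio of female over male correlated between preparations 18 and 19 with r of 0.204 on 22K-1 and 0.298 on 22K-2, and between preparation 23 and either of them with r from −0.000889 to 0.0393 on 22K-1 and from 0.0514 to 0.0932 on 22K-2. By rank, Spearman's rho was 0.283 and 0.303 between preparations 18 and 19, and between preparation 23 and either of them it was below 0, from −0.106 to −0.0611 on 22K-1 and from −0.109 to −0.0985 on 22K-2. Features are not independent replicates. Of the sum of squared ratios, 15.8% on 22K-1 and 16.1% on 22K-2 lay in the mean of female over male, 1 of 6 components. Equal noise in all components would put 16.7% there, but the components were not equal, as the mean dye part, also 1 of 6, held 34.8% and 41.6%. The differences of female over male between preparations, 2 of 6 components, held 26.0% and 22.1%. All 6 arrays had the same sign for 769 features of 22K-1 and 805 of 22K-2. With the sexes exchanged within preparation 23 there were more, 961 and 1039, and with those of preparation 18 or 19 exchanged there were fewer, from 227 to 262 on 22K-1 and from 238 to 260 on 22K-2. The control-like features of both sets shared 320 feature numbers.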
